A study of Mus musculus with 6 samples.

How the data were processed

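Small RNA was sequenced from mouse placentas at stage E18.5, late in gestation. The labels give 3 libraries from Ago2+/+ (wild-type) placentas and 3 from placentas homozygous for Ago2 D598A, an allele with a substitution in the catalytic centre of the slicing nuclease AGO2. Per the labels' protocols, RNA was extracted with TRIzol and treated with TURBO DNase, and libraries were made with the NEBNext kit for small RNA. The submitters' processing notes name cutadapt 4.7, STAR, Subread and featureCounts 2.0.3. The role and order of these tools, the genome build, the reference for mature miRNAs, the normalisation method and any filter on low counts were not given in the sources used here.

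The values are a normalised signal per mature miRNA and library, made and deposited by the authors as normalised counts, per the file headers. The table holds 679 mature mouse miRNAs, with no zero value. The median ratio of a library to the geometric mean over libraries was 1.00035 in each of the 6, as it is after scaling by the median of ratios. Low values moved in steps of a fixed size per library, taken here as the value of 1 read. Of the values under 500, 78.9% to 84.8% per library lay within 0.05 reads of a whole number of steps. The remaining values were fractional, as when a read is divided between miRNAs, so whole reads were not recovered and tests that need them were left out. The deposited columns for start, stop and length, of another unit per the file headers, give positions on the mature sequence itself. Lengths ran from 17 to 27 nt, and these columns were used in no test.

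The sum of values per library divided by the size of 1 step gave the estimated depth. It was 5706426, 21230641 and 21168270 reads in wild-type replicates 1, 2 and 3, and 11020457, 10958059 and 19857225 reads in Ago2 D598A replicates 1, 2 and 3. The smallest value in any library stood for 10.4 estimated reads, and the lowest mean over the 6 libraries was a value of 16.4, so miRNAs below this level are outside the comparison. Counting error came to 22.4% to 31.0% of the smallest value and 3.43% to 6.88% of the median value. These figures cover counting error alone, since reads amplified by PCR are not independent molecules.

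The tests, miRNA lists, alternatives and the rule for named miRNAs were fixed before the data were examined. Genotypes were compared with limma 3.58.1 in R 4.3.3 on log2(value + 1), with lmFit and eBayes with trend, 2-sided. A Benjamini-Hochberg adjusted p below 0.05 counted as changed. miRNAs with a mean of at least 10 were tested, which removed 0 of the 679. Fold changes are Ago2 D598A over wild-type, and standard errors are those of the moderated limma fit. All adjusted p-values of single miRNAs and arm ratios in the text are from this limma test. The labels do not say whether the placentas came from separate dams or litters, so the p-values measure spread between these samples.

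The 17 lists were the AGO2 slicer-dependent miRNAs, the anti-Rtl1 miRNAs, the other miRNAs of the Dlk1-Dio3 region, the Sfmbt2 cluster, the cluster of miR-322 and miR-503, miR-675 of H19, miR-17-92 with its paralogous clusters, the let-7 family, miR-210 as a hypoxia marker, and markers of endothelium, smooth muscle with pericytes, red cells outside slicing, leukocytes, epithelium, striated muscle, nervous tissue and liver. They were written from general knowledge of placental cell types, AGO2 and the Rtl1 region, and none was chosen on these samples. Several markers are expressed by more than 1 cell type of the placenta, so a list names a cell type only loosely. The 14 lists with at least 3 members were tested with limma's camera at a preset correlation of 0.01, adjusted over the 14 lists, with the estimated correlation and limma's fry beside it. Adjusted p-values of lists are from camera unless fry is named. Every member of the slicer-dependent and anti-Rtl1 lists was named whatever its p. The 10 changed miRNAs with the largest rise and the 10 with the largest fall were also named. From each other list, up to 4 changed members were named, or the 2 with the highest mean where none changed. Any miRNA outside this rule is marked as chosen after its values were seen.

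A miRNA hairpin gives a 5p and a 3p arm, and the arm with the higher mean was taken as the major arm. For 196 hairpins with both arms in the table, limma with trend was run on log2((lesser + 1)/(major + 1)) with the same threshold. The share of the summed values taken by each list was compared by a 2-sided exact permutation test over 20 arrangements, adjusted over the 17 lists. With 3 libraries against 3, its smallest possible p is 0.1. The miRNA names were matched to hairpin genes of the RefSeq table of assembly GRCm38.p6, which gave positions for 631 of 679 miRNAs, and the overlapping genes were read from GENCODE M21 annotation of the same assembly. Sequences of 456 hairpin genes were folded with RNAfold 2.7.2. A total of 22 miRNAs in 10 sets had values identical to another miRNA in all 6 libraries, and these cannot be told apart by the counting. Shares and permutation tests used Python 3.11.15 with scipy 1.17.1.

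The tests were also tested on simulated libraries, drawn with the real means and the real spreads shuffled between miRNAs. In 20 simulated runs of the miRNA test on 679 miRNAs with 200 changed, 77.4% of changes of 0.75 log2 and 96% of changes of 1.5 log2 were recovered, with 3.66% false calls. The arm ratio test on 196 hairpins with 60 changed recovered 69.2% and 96.7% at the same sizes, with 3.67% false calls. Simulated changes outnumbered the 82 miRNAs and 41 arm ratios called in the real libraries. A smaller changed share makes the adjusted threshold stricter, so recovery in the real data may be lower. The list test called the let-7 family, shifted by 0.5 log2, in 20 of 20 runs and made 0 calls on the unshifted lists. The real let-7 median was smaller, at 0.20 log2. In the real libraries, groupings of 3 against 3 that mixed the genotypes called up to 5 lists. The 0 calls in simulation therefore cannot be carried over to the real lists, although such groupings still keep part of any genotype difference. The alternatives were pseudocounts of 0.5, 5 and 10, no filter, a filter at a mean of 50, other scalings, limma without trend or with robust eBayes, the replicate number as a block, other list tests, and leaving out each library in turn. limma-voom on estimated reads, identical miRNAs counted once, and a model with estimated depth were added after the data were seen.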

Results

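Mature miRNAs were quantified by small RNA sequencing in 6 mouse placentas collected at stage E18.5, near the end of gestation. Of these, 3 were wild-type and 3 were homozygous for Ago2 D598A, which carries a substitution in the catalytic centre of AGO2, the Argonaute protein that can cut RNA paired to its guide. A point substitution leaves no trace in a table of small RNAs, so the genotypes could not be checked from these values. Estimated depth was 5706426 to 21230641 reads in the wild-type libraries and 10958059 to 19857225 reads in the Ago2 D598A libraries. Values below are the authors' normalised read counts, given as mean ± SD with n = 3 per genotype, with wild-type first. The sums of the values were 13304377 to 14234622 per library, and the 10 most abundant miRNAs took 46.4% to 47.9% of each sum. miR-26a-5p was the most abundant miRNA in the wild-type libraries and in Ago2 D598A replicate 1, and let-7i-5p in the remaining Ago2 D598A libraries. Replicates of the same genotype correlated at 0.992 to 0.996 on the log2 scale (Pearson).

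The study's title places AGO2 cutting of a domesticated retrotransposon, Rtl1, beside the formation of blood vessels. The comparison asks which miRNAs differ between wild-type and Ago2 D598A placentas. Values are per library, so cells of the mother and of the fetus within a placenta cannot be told apart.

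The mature strands known to depend on AGO2 cutting were lower in the mutant placentas. miR-451a, a red cell miRNA whose precursor is cut by AGO2 in place of Dicer, fell 2.42-fold, from 21202 ± 2659.9 to 8703 ± 459.8 (SD, n = 3), and every mutant library lay below every wild-type library. Its log2 fold change was -1.28 (SE 0.12, adjusted p = 1.4e-04). miR-486a-5p and miR-486b-5p, which have identical values here and cannot be told apart, fell from 20940.5 ± 2395 to 13185 ± 630 (log2 fold change -0.66, SE 0.12, adjusted p = 0.00695). The opposite arm, miR-486a-3p, which AGO2 is known to cut as the passenger strand, was at 286 ± 55.9 and 410.5 ± 150 and did not pass (log2 fold change 0.46, adjusted p = 0.335). It passed without Ago2 D598A replicate 2 (adjusted p = 0.0465, log2 fold change 0.81) and was furthest from passing without Ago2 D598A replicate 3 (adjusted p = 0.654). With a library left out, its log2 fold change ran from 0.27 to 0.81. Relative to the major arm, however, miR-486a-3p rose, from 1.36 ± 0.155 to 3.11 ± 1.09 reads per 100 reads of miR-486a-5p (log2 change 1.12, adjusted p = 0.0197).

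Of the 4 members of this list, 3 fell and 1 did not pass, and the count adjusted over the list alone was also 3. As miR-486a-5p and miR-486b-5p are 1 profile counted 2 times, the 3 falls are 2 distinct profiles. As a set they were lower by camera (adjusted p = 0.0104), with adjusted p = 0.486 with an estimated correlation and adjusted p = 0.0427 by fry. Their share of the summed values went from 0.475% ± 0.0265 to 0.258% ± 0.004, a difference of -0.217 points at the smallest p that 3 libraries against 3 can give (exact permutation p = 0.1, adjusted 0.283). With identical miRNAs counted once, an alternative chosen after seeing the data, camera gave adjusted p = 0.0442 and the share went from 0.321% ± 0.0147 to 0.163% ± 0.0044 (exact permutation p = 0.1). The calls of miR-451a and miR-486a-5p held with each library left out.

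The gene of miR-451a (Mir451a) lies on chromosome 11 at 78073170 to 78073241 on the plus strand of GRCm38.p6, overlapping no other annotated gene. Its 72-nt hairpin, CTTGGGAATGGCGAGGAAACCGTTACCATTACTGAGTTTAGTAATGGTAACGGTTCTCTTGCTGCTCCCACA, folded with a longest uninterrupted helix of 17 base pairs and a minimum free energy of -43.3 kcal/mol. Mir144, which is made from the same primary transcript, lies at 78073005 to 78073070. Mir486 lies on chromosome 8 at 23142555 to 23142682, in an intron of Ank1.

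No member of the list of red cell miRNAs outside slicing passed the test as lower. miR-144-5p, which like the other unchanged members named here was chosen after its values were seen, was at 4495 ± 244 and 4758 ± 642 (log2 fold change 0.07, adjusted p = 0.781). Its lesser arm miR-144-3p rose from 58.1 ± 33 to 181 ± 67.8 (log2 fold change 1.69, adjusted p = 0.019). That call ended without wild-type replicate 2 or Ago2 D598A replicate 1 or 2 (each in turn; adjusted p = 0.0727, 0.0912 and 0.0652). Of the 5 members of the list, 1 rose and 4 did not pass, among them miR-106a-5p (log2 fold change -0.42), miR-20b-5p (-0.23) and miR-363-3p (0.12). The count adjusted over the list alone was also 1 (camera adjusted p = 0.825). This list names red cells only loosely. Its result does not show that red cell miRNAs other than miR-144 held steady.

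**Figure D1:**
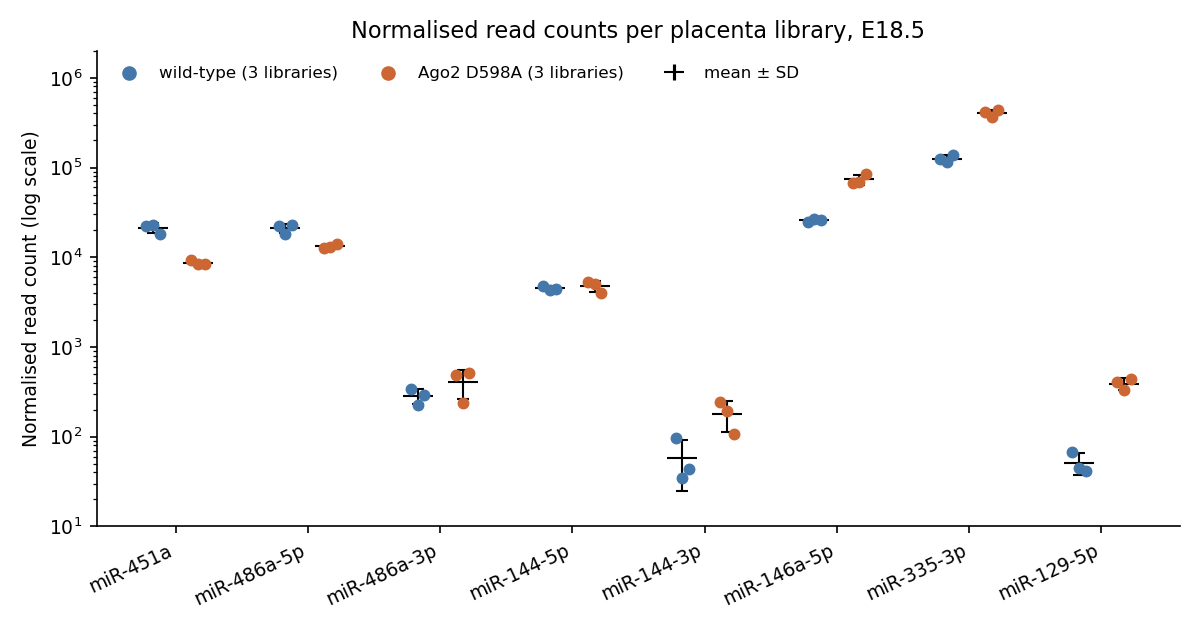
Normalised read counts (log scale) of 8 miRNAs in 3 wild-type and 3 Ago2 D598A placentas; dots are libraries, and black bars are mean ± SD. miR-451a and miR-486a-5p lay lower in every mutant library, miR-144-5p overlapped between genotypes, and miR-335-3p, miR-146a-5p and miR-129-5p lay higher in every mutant library.

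The miRNAs antisense to Rtl1 showed no common direction. They are made from the maternal copy of the region and pair perfectly with the mRNA of Rtl1, the retrotransposon-derived gene that the placenta needs for its fetal capillaries. miR-431-3p rose from 7309 ± 469 to 11330.4 ± 1320.1 (log2 fold change 0.63, SE 0.13, adjusted p = 0.0118) and miR-136-3p fell from 20656 ± 2262 to 14168 ± 1119.6 (log2 fold change -0.54, SE 0.12, adjusted p = 0.0188). The most abundant, miR-127-3p, was at 421646 ± 92313 and 466309 ± 100802 (log2 fold change 0.15, adjusted p = 0.646), and its change turned negative without wild-type replicate 1 or Ago2 D598A replicate 3. miR-433-3p was at 45508 ± 10428 and 63935 ± 11858 (log2 fold change 0.50, adjusted p = 0.0939) and miR-433-5p had a log2 fold change of 0.45 (adjusted p = 0.0898); both passed when adjusted over the list alone (adjusted p = 0.0469) and with the replicate number as a block (adjusted p = 0.00589 and 0.0337).

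The other members did not pass: miR-127-5p (log2 fold change 0.17, adjusted p = 0.395), miR-434-5p (0.17, 0.421), miR-434-3p (-0.12, 0.615), miR-136-5p (-0.17, 0.352) and miR-431-5p (0.11, 0.662). Of the 10 arms, 1 rose, 1 fell and 8 did not pass; adjusted over the list alone, 3 rose and 1 fell. miR-432 was not in the table. The set was not called by camera (adjusted p = 0.368), and its share of the summed values went from 4.66% ± 0.78 to 4.99% ± 0.691 (exact permutation p = 0.6, with 0.1 the smallest possible). The miR-431-3p call ended without Ago2 D598A replicate 1 (adjusted p = 0.0519). The miR-136-3p call ended without wild-type replicate 2 or Ago2 D598A replicate 2 or 3 (each in turn; adjusted p = 0.0595, 0.0758 and 0.0505). miR-433-3p passed without wild-type replicate 3 (adjusted p = 0.0323), and its log2 fold change was 0.33 without wild-type replicate 2.

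Rtl1 lies on chromosome 12 at 109589193 to 109600330 on the minus strand of GRCm38.p6. The 5 hairpins lie on the plus strand opposite an exon of Rtl1: Mir431 at 109590447 to 109590537, Mir433 at 109591715 to 109591838, Mir127 at 109592846 to 109592915, Mir434 at 109594506 to 109594599 and Mir136 at 109595327 to 109595388. Rtl1 mRNA itself was not measured by this assay.

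**Figure D2:**
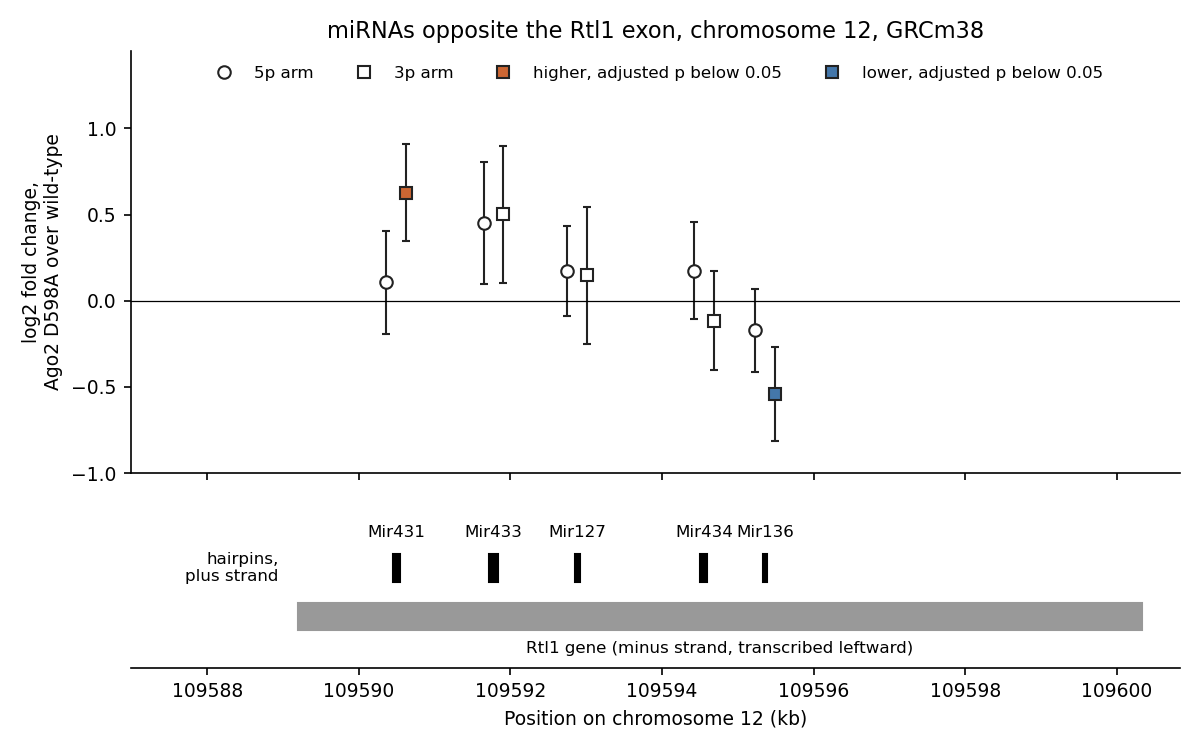
Log2 fold change (Ago2 D598A over wild-type) of the 10 anti-Rtl1 arms with 95% confidence intervals from limma, placed along chromosome 12 (kb, GRCm38.p6) above the Rtl1 gene and its 5 antisense hairpins. miR-431-3p lay above 0 and miR-136-3p below 0 at an adjusted p under the threshold; the other 8 arms did not pass.

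The list of other miRNAs of the Dlk1-Dio3 region, the imprinted domain that holds Rtl1, does not cover the whole region: miR-3544, for one, is not on it. Of its 77 members, 12 rose, 8 fell and 57 did not pass; adjusted over the list alone, 16 rose and 9 fell. miR-666-5p rose from 2485 ± 204 to 6876 ± 666 (log2 fold change 1.47, adjusted p = 7.3e-05) and miR-299a-3p from 6485 ± 829 to 20578 ± 7428 (log2 fold change 1.60, adjusted p = 0.00366). miR-770-5p, within an exon of Meg3, rose from 249 ± 43.8 to 646 ± 88.7 (log2 fold change 1.38, adjusted p = 9.1e-04), miR-493-3p from 793 ± 52.3 to 1725 ± 134 (log2 fold change 1.12, adjusted p = 4.7e-04) and miR-154-3p from 4476 ± 353 to 7754 ± 502 (log2 fold change 0.79, adjusted p = 0.0032). miR-496a-3p, in an intron of Mirg like miR-154-3p, fell from 159 ± 10.7 to 82.9 ± 16.7 (log2 fold change -0.95, adjusted p = 0.0136), a call that ended without Ago2 D598A replicate 2 (adjusted p = 0.0529). The set's median log2 fold change was 0.21 (0.12 without wild-type replicate 2) and camera called it higher (adjusted p = 0.0161), with adjusted p = 0.553 with an estimated correlation and adjusted p = 0.138 by fry. The camera call ended without wild-type replicate 1 (adjusted p = 0.0536), wild-type replicate 2 (0.0857), Ago2 D598A replicate 1 (0.0563) or Ago2 D598A replicate 3 (0.0671). The share of the summed values went from 6.14% ± 0.6 to 7.03% ± 0.452 (exact permutation p = 0.2).

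Across all 679 miRNAs, 82 changed (12.1%), 45 of them higher and 37 lower in the mutant placentas. miR-129-5p rose most, 7.60-fold from 51.5 ± 14.2 to 392 ± 56.6 (log2 fold change 2.93, adjusted p = 2.9e-05); its name matched no position in the gene table. The abundant miR-335-3p, from an intron of the imprinted gene Mest on chromosome 6 (30741299 to 30741396), rose 3.20-fold from 125800 ± 10738 to 402723 ± 35999 (log2 fold change 1.68, adjusted p = 1.0e-05). miR-146a-5p, a miRNA induced by NF-kB signalling (chromosome 11, 43374397 to 43374461), rose from 25792 ± 1247 to 73685 ± 9533 (log2 fold change 1.51, adjusted p = 2.9e-05). The other large rises were miR-139-3p from an intron of Pde2a (452 ± 88.7 to 1645 ± 514, log2 fold change 1.83, adjusted p = 5.3e-04), miR-3544-5p, between Meg3 and Rtl1 on chromosome 12 (336 ± 58.1 to 988 ± 126, log2 fold change 1.56, adjusted p = 3.0e-04), miR-6944-3p (201 ± 3.69 to 573 ± 54.8, adjusted p = 1.2e-04) and the muscle miRNA miR-206-3p (22.2 ± 11.2 to 63.4 ± 7.81, log2 fold change 1.57, adjusted p = 0.0142). The call of miR-206-3p ended without wild-type replicate 2 or Ago2 D598A replicate 1 (each in turn; adjusted p = 0.0547 and 0.0519).

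Among the largest falls, miR-2137, in an intron of Zfp185 on chromosome X (72992079 to 72992144), went from 1019 ± 404 to 241 ± 149 (log2 fold change -2.17, adjusted p = 0.0119). miR-6239, opposite an intron of Gpc6 on chromosome 14 (117953743 to 117953847), went from 24494 ± 9851 to 6057 ± 2192 (log2 fold change -1.98, adjusted p = 0.00366). miR-6240 (242 ± 169 to 62.8 ± 14.4, log2 fold change -1.73, adjusted p = 0.0206), miR-6236 (199 ± 113 to 67.8 ± 8.76, log2 fold change -1.40, adjusted p = 0.0222) and miR-6238 (70.2 ± 7.78 to 34.6 ± 4.43, adjusted p = 0.0184) fell as well. miR-204-5p, from an intron of Trpm3, fell from 236 ± 13.3 to 113 ± 28.5 (log2 fold change -1.09, adjusted p = 0.00695). miR-652-5p fell from 60.1 ± 12.3 to 25.5 ± 1.08 (log2 fold change -1.18, adjusted p = 0.0134) and miR-6937-5p from 89.3 ± 76.3 to 19.1 ± 8.28 (log2 fold change -1.91, adjusted p = 0.0404). The miR-2137 call ended without wild-type replicate 2 or Ago2 D598A replicate 1 (each in turn; adjusted p = 0.0547 and 0.0519). The miR-6240 call ended without Ago2 D598A replicate 1 or 3 (each in turn; adjusted p = 0.0809 and 0.0642). The miR-6236 call ended without wild-type replicate 2 or Ago2 D598A replicate 1, 2 or 3 (each in turn; adjusted p = 0.0547, 0.0702, 0.0732 and 0.0642). The miR-6238 call ended without wild-type replicate 2 or Ago2 D598A replicate 2 (each in turn; adjusted p = 0.0607 and 0.0567). The miR-652-5p call ended without wild-type replicate 2 (adjusted p = 0.0547). The miR-6937-5p call ended without wild-type replicate 1 or 2 or Ago2 D598A replicate 1 or 3 (each in turn; adjusted p = 0.0508, 0.104, 0.135 and 0.108). It also ended with a pseudocount of 10 (adjusted p = 0.0521), limma without trend (0.0759), robust eBayes (0.0592) and limma-voom (0.0782, chosen after seeing the data), and its log2 fold change was -1.26 without wild-type replicate 2. With limma without trend the calls of miR-6240 (adjusted p = 0.0515) and miR-6236 (0.0518) ended too.

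The median size of the log2 fold change of the 82 was 0.74 and the smallest was 0.39. An unadjusted p below 0.05 was reached by 185 miRNAs, and 219 had genotypes that did not overlap (32.3% of 679, where chance gives 10%). The first principal component held 52.0% of the variance and separated the genotypes. Of the 82, 28 were called whichever library was left out; the count was 47 without wild-type replicate 2, 39 without Ago2 D598A replicate 1 and 44 without Ago2 D598A replicate 2.

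**Figure D3:**
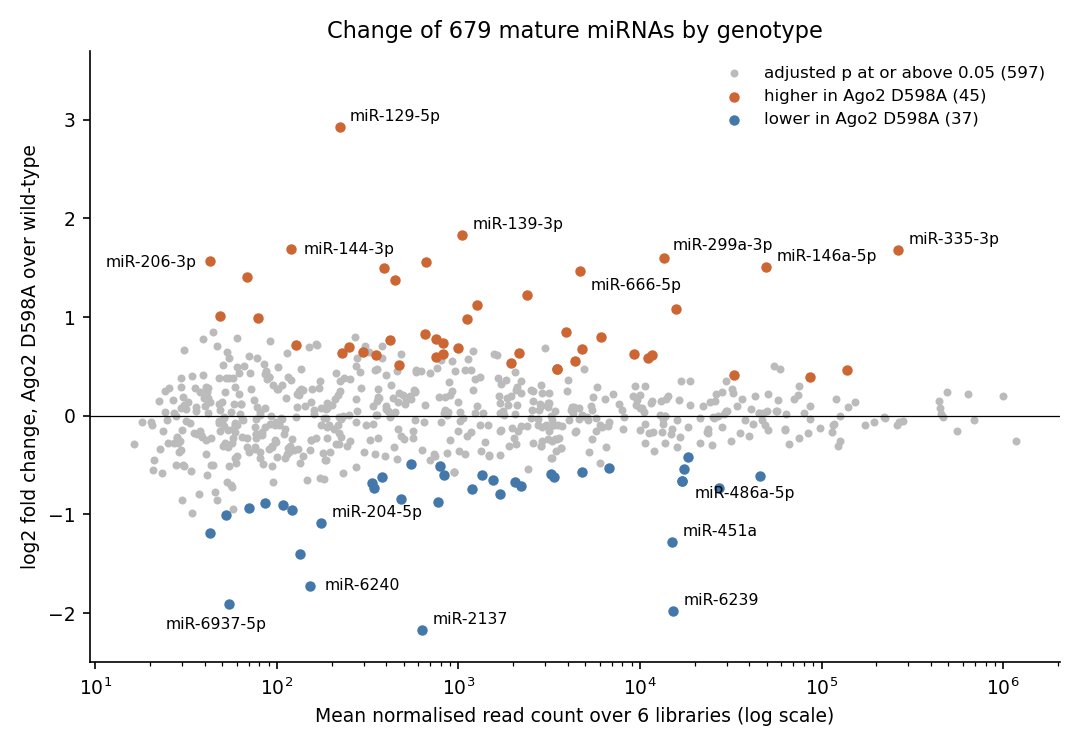
Log2 fold change (Ago2 D598A over wild-type) of 679 miRNAs against their mean normalised read count over 6 libraries (log scale). Each point is a miRNA; 45 were higher (orange), 37 lower (blue) and 597 did not pass (grey), and changed miRNAs occur over most of the abundance range.

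Among endothelial miRNAs 2 of 9 passed, against 12.1% of all miRNAs, and no stromal marker did. The abundant endothelial miR-126a-3p was at 448945 ± 20084 and 532131 ± 24232 (log2 fold change 0.25, adjusted p = 0.0817; chosen after its values were seen), while its partner arm miR-126a-5p fell from 8023 ± 668 to 5545 ± 524 (log2 fold change -0.53, adjusted p = 0.0206) and miR-222-3p fell from 929 ± 41.6 to 655 ± 40.8 (log2 fold change -0.51, adjusted p = 0.0262). Of 9 endothelial members, 2 fell and 7 did not pass. Adjusted over the list alone, 1 rose and 3 fell. As a set the 9 members were called neither by camera (adjusted p = 0.301) nor by fry (adjusted p = 0.0535, lower). Their median log2 fold change was -0.43, but only -0.13 without wild-type replicate 2 and -0.27 without Ago2 D598A replicate 2. Their share of the summed values, most of it miR-126a-3p, went from 3.48% ± 0.145 to 3.95% ± 0.204 (exact permutation p = 0.1). The miR-126a-5p call ended without wild-type replicate 2 or 3 or Ago2 D598A replicate 1 or 2 (each in turn; adjusted p = 0.0638, 0.0556, 0.0519 and 0.0933). The miR-222-3p call ended without wild-type replicate 2 or 3 or Ago2 D598A replicate 1, 2 or 3 (each in turn; adjusted p = 0.0757, 0.0689, 0.114, 0.0819 and 0.051). None of the 4 smooth muscle and pericyte members passed, with log2 fold changes of -0.05 for miR-143-3p and 0.24 for miR-145a-5p (camera adjusted p = 0.368).

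Among epithelial miRNAs, 2 lesser arms of the miR-200 family fell. miR-200a-5p fell from 1002 ± 95.5 to 546 ± 21 (log2 fold change -0.87, adjusted p = 0.00327) and miR-200b-5p from 111 ± 7.55 to 60.1 ± 8.08 (log2 fold change -0.88, adjusted p = 0.0172), and the other 10 of 12 members did not pass (adjusted over the list alone, 4 fell). Camera called the set lower (adjusted p = 0.0161), with adjusted p = 0.486 with an estimated correlation and adjusted p = 0.0484 by fry. The share of the summed values went from 2.16% ± 0.079 to 1.98% ± 0.11 (exact permutation p = 0.1). The miR-200b-5p call ended without Ago2 D598A replicate 2 (adjusted p = 0.0681), and the camera call ended without wild-type replicate 1 (0.0536) or Ago2 D598A replicate 3 (0.0778).

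Among 7 leukocyte members, miR-146a-5p alone rose and the other 6 did not pass. Log2 fold changes, chosen for print after they were seen, were 0.58 for miR-142a-5p (adjusted p = 0.116) and 0.30 for miR-142a-3p. They were -0.06 for miR-223-3p, -0.30 for miR-150-5p and 0.10 for miR-155-5p. The list was not called by camera (adjusted p = 0.301; adjusted p = 0.0484 by fry), and its median of 0.10 ran from -0.03 to 0.24 with a library left out. Its share of the summed values, most of it miR-146a-5p, went from 0.268% ± 0.00582 to 0.616% ± 0.0414 (exact permutation p = 0.1, adjusted 0.283). Of 3 striated muscle members, 1 rose, miR-206-3p, and the median ran from -0.10 to 0.17 with a library left out (camera adjusted p = 0.447). For both lists the count adjusted over the list alone was also 1. None of 5 neural members passed (miR-128-3p 0.06, miR-9-5p -0.28; camera adjusted p = 0.686), nor did the liver marker miR-122-5p (log2 fold change -0.42, adjusted p = 0.435).

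Few single members of clusters abundant in placenta passed the test. In the Sfmbt2 cluster, a multicopy rodent placental family, 52 of 58 members had negative log2 fold changes with a median of -0.25 (-0.15 without wild-type replicate 2), although the test was passed only by miR-467b-5p (1898 ± 202 to 1207 ± 36.8, log2 fold change -0.65, adjusted p = 0.0118) and miR-669b-3p (144 ± 50 to 73.9 ± 8.64, log2 fold change -0.90, adjusted p = 0.0389), both lower; adjusted over the list alone, 1 fell. The 58 members of this cluster have 51 distinct profiles, as when copies share reads, so single members are uncertain. Of 12 members of the X-linked cluster of miR-322 and miR-503, 2 fell, miR-351-3p (1479 ± 166 to 887 ± 111, log2 fold change -0.74, adjusted p = 0.0118) and miR-542-3p (55864 ± 12353 to 36186 ± 3508, log2 fold change -0.61, adjusted p = 0.0252), as they did adjusted over the list alone. Camera called both clusters lower (adjusted p = 3.0e-05 and 0.0161), with adjusted p = 0.486 for each with an estimated correlation and adjusted p = 0.138 and 0.0545 by fry. Their shares of the summed values went from 1.65% ± 0.0956 to 1.452% ± 0.0692 and from 4.1% ± 0.262 to 3.51% ± 0.251 (exact permutation p = 0.1 for each). In miR-17-92 and its paralogous clusters, 1 of 17 members fell, miR-18a-3p (424 ± 38.4 to 257 ± 51.3, log2 fold change -0.73, adjusted p = 0.0222), also 1 adjusted over the list alone (camera adjusted p = 0.301). The miR-467b-5p call ended without Ago2 D598A replicate 1 (adjusted p = 0.0519). The miR-669b-3p call ended without wild-type replicate 2 or Ago2 D598A replicate 1, 2 or 3 (each in turn; adjusted p = 0.106, 0.0809, 0.118 and 0.0845). The miR-351-3p call ended without Ago2 D598A replicate 1 or 2 (each in turn; adjusted p = 0.0519 and 0.0512). The miR-542-3p call ended without wild-type replicate 2 or Ago2 D598A replicate 1, 2 or 3 (each in turn; adjusted p = 0.0607, 0.0588, 0.0876 and 0.0804). The miR-18a-3p call ended without wild-type replicate 1 or 2 or Ago2 D598A replicate 1 or 2 (each in turn; adjusted p = 0.0514, 0.0785, 0.0858 and 0.0602). With limma without trend the calls of miR-669b-3p (adjusted p = 0.0533) and miR-542-3p (0.0759) ended.

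The let-7 family, abundant in most differentiated tissues, was higher in 5 of 21 members and none fell. let-7d-3p rose from 3711 ± 352 to 5911 ± 129 (log2 fold change 0.68, adjusted p = 0.00695), let-7b-5p from 9262 ± 1166 to 14126 ± 792 (log2 fold change 0.62, adjusted p = 0.0134), and let-7c-2-3p and let-7a-1-3p, with identical values, from 2940.4 ± 242 to 4074 ± 311 (log2 fold change 0.47, adjusted p = 0.0351). The fifth was let-7f-1-3p (outside the naming rule), and 6 rose adjusted over the list alone. All of the 5 but let-7b-5p were 3p arms. The major arm let-7d-5p, chosen after its values were seen, did not pass (log2 fold change -0.025, adjusted p = 0.902). Camera called the family higher (adjusted p = 0.00479), with adjusted p = 0.486 with an estimated correlation and adjusted p = 0.0535 by fry. Its share of the summed values was 18.3% ± 1.48 and 18.7% ± 0.751 (exact permutation p = 0.7). The shared call of let-7c-2-3p and let-7a-1-3p ended without wild-type replicate 2 or 3 or Ago2 D598A replicate 1, 2 or 3 (each in turn; adjusted p = 0.1, 0.066, 0.121, 0.0652 and 0.0981), and with equal library sums (0.0503) or limma without trend (0.0655). The hypoxia-induced miR-210-3p (log2 fold change -0.04, adjusted p = 0.879), miR-210-5p (log2 fold change -0.77, adjusted p = 0.0608), and the H19 miRNAs miR-675-5p (log2 fold change 0.19, adjusted p = 0.432) and miR-675-3p (log2 fold change -0.67, adjusted p = 0.0505) did not pass in the main test; adjusted over each list alone, 1 of each pair fell. miR-675-3p lay near the threshold. It passed without wild-type replicate 3 (adjusted p = 0.0499), with the filter at a mean of 50 (0.0467), equal library sums (0.0414), TMM (0.0441), limma without trend (0.0399), robust eBayes (0.0497) and the block (0.0308). miR-210-5p passed with equal library sums (0.0479), limma without trend (0.0247) and the block (0.0416).

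In part of the hairpins the ratio between the arms changed, and the hairpins named here were chosen after their values were seen. miR-335-3p rose without its partner, so that miR-335-5p went from 34.8 ± 6.04 to 10.2 ± 1.65 reads per 100 reads of miR-335-3p (log2 change -1.77, adjusted p = 0.00144). For miR-666 the lesser arm went from 2.11 ± 0.196 to 0.759 ± 0.151 per 100 reads of the major arm (log2 change -1.49, adjusted p = 0.00144), for miR-700 from 41.5 ± 3.22 to 15.4 ± 2.74 (log2 change -1.44, adjusted p = 0.00144) and for miR-3544 from 58.9 ± 8.29 to 25.5 ± 2.14 (log2 change -1.20, adjusted p = 0.00187). The lesser arm gained ground in miR-1981, from 9.09 ± 0.747 to 24.3 ± 3.22 per 100 (log2 change 1.41, adjusted p = 0.00144), in miR-139, from 1.59 ± 0.204 to 4.32 ± 0.984 (log2 change 1.43, adjusted p = 0.00187), and in miR-144, from 1.29 ± 0.648 to 3.74 ± 0.968 (log2 change 1.61, adjusted p = 0.0122).

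Of 196 hairpins, 41 changed their arm ratio, 13 with a relatively higher and 28 with a relatively lower lesser arm (exact binomial p = 0.0275, 2-sided). That binomial test counts hairpins as independent, although all come from the same 6 libraries. Its p does not measure spread between placentas. As single miRNAs, only the lesser arm passed in 19 of the 41, only the major arm in 11, both in 1 and neither in 10. The median log2 ratio of lesser to major arm per library was -3.18 ± 0.12 and -3.32 ± 0.10, a difference within the spread of the libraries (exact permutation p = 0.3). The number of changed ratios was 25 without wild-type replicate 2, 20 without wild-type replicate 3 and 27 without Ago2 D598A replicate 2.

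**Figure D4:**
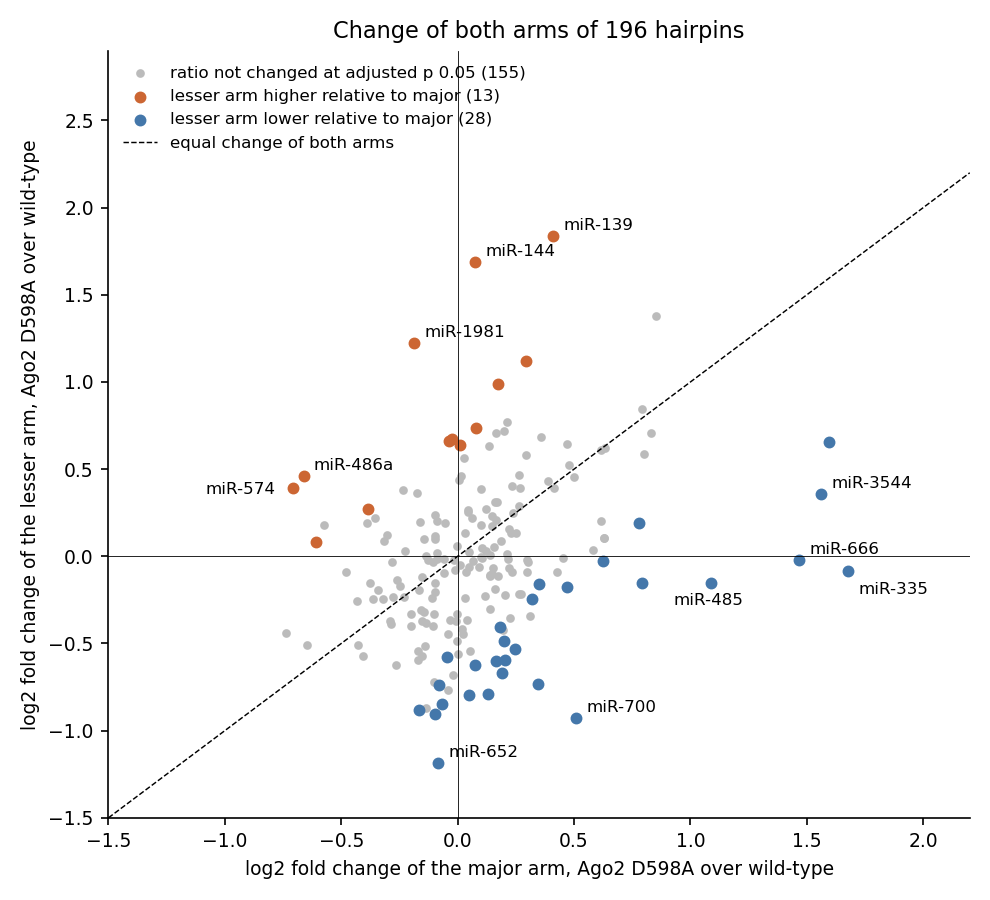
Log2 fold change (Ago2 D598A over wild-type) of the lesser arm against that of the major arm for 196 hairpins; the dashed line marks equal change of both arms. The ratio changed in 41 hairpins, with the lesser arm relatively higher in 13 (orange, above the line) and relatively lower in 28 (blue, below the line).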

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

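With limma and Benjamini-Hochberg adjustment, each of the 82 changed miRNAs kept its sign in every setting that tested it. The alternatives on pseudocount, filter, scaling and moderation gave 71 (limma without trend, 64 of them among the 82) to 87 changed miRNAs (quantile normalization, 74 among the 82). limma-voom gave 82 and counting identical miRNAs once gave 81, and both were chosen after seeing the data. A model with estimated depth added, also chosen after seeing the data, gave 120. The signs of the 82 were not compared under that model. Skipping the filter and rescaling by the median of ratios left the count at 82, since they change next to nothing here. The filter at a mean of 50 left out miRNAs with low values, and 79 of the 82 were tested under it. The largest shift of the median log2 fold change over all miRNAs was -0.0446, with equal library sums.

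The replicate number as a block raised the count to 150, with 84 higher and 66 lower, and all 82 among them. The deviations of same-numbered libraries correlated at 0.211, 0.0543 and 0.523, and those of differently numbered libraries at -0.376 to 0.264. With 3 libraries per genotype, these values cannot show whether the numbers mark pairs, and the labels do not say. The block was therefore kept as an alternative only. With an estimated correlation, camera called 0 of 14 lists, against 6 with the preset one, and fry called 3. In those 6 lists the estimated correlation was 0.0477 to 0.286, above the preset 0.01. A higher correlation within a list weakens its camera result. How far this alone accounts for the lost calls was not tested.

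Leaving out each library in turn, which also means fewer samples, gave 39 to 86 changed miRNAs, 21 to 44 higher and 17 to 42 lower. The count was 47 without wild-type replicate 2, 39 without Ago2 D598A replicate 1 and 44 without Ago2 D598A replicate 2. Changed arm ratios numbered 20 to 46, with the lesser arm up in 5 to 16 and down in 15 to 30. They numbered 25 without wild-type replicate 2, 20 without wild-type replicate 3 and 27 without Ago2 D598A replicate 2. The lists called by camera numbered 4 to 6. The difference in share was -0.231 to -0.205 points for the slicer-dependent miRNAs and -0.0401 to 0.743 points for the anti-Rtl1 miRNAs, which takes in both signs. Among named miRNAs with a library left out, 277 results kept their sign and side of the threshold, 60 became weaker, 3 stronger and 8 changed sign. Under the other settings except the block, 729 kept both, 12 became weaker, 7 stronger and 1 changed sign. Every change of sign was in a result that did not pass. With a library left out, the log2 fold change of miR-127-3p ran from -0.0246 to 0.298, of miR-128-3p from -0.105 to 0.152, of miR-210-3p from -0.164 to 0.0567 and of miR-434-3p from -0.194 to 0.0116 (0.01004 with quantile normalization). The list medians ran from -0.141 to 0.188 for red cells outside slicing (-0.0755 with the filter at a mean of 50), -0.03005 to 0.241 for leukocytes (-0.0065 with quantile normalization), -0.105 to 0.0597 for neural and -0.103 to 0.174 for striated muscle members (-0.0379 with equal library sums, -0.0227 with TMM, -0.00152 with quantile normalization). Counting identical miRNAs once, also chosen after seeing the data, gave 6 lists and a slicer-dependent share difference of -0.157 points. The planned count-model tests on recovered whole reads were not run, because whole reads could not be recovered. Depth limits the low miRNAs: the smallest value of a library carried a counting error of up to 31.0%.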

Other observations

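Tests on red blood cells, on the slope with depth, on shared reads and on the lower lesser arms, and the count of splits for changed miRNAs, were chosen after the result was seen; the other tests below were fixed earlier.

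Several other miRNAs, picked here after their values were seen, also changed. miR-485-3p of the Dlk1-Dio3 region rose (log2 fold change 1.09, adjusted p = 0.00366), while miR-411-3p (log2 fold change -0.80, adjusted p = 0.00366) and miR-379-5p (log2 fold change -0.74, adjusted p = 0.00695) of the same region fell. miR-1981-3p rose from 1433 ± 142 to 3361 ± 485 (log2 fold change 1.22, adjusted p = 5.1e-04), and miR-574-3p fell from 2754 ± 179.7 to 1691 ± 223 (log2 fold change -0.71, adjusted p = 0.0105). Of the 82 changed miRNAs, 40 belonged to no fixed list.

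miR-451a fell while the arms of miR-144, cut from the same primary transcript, did not fall. Fewer red blood cells in the mutant placentas would lower all of these together, if miR-144 per red cell stayed the same. The log2 change exceeded that of miR-451a by 1.35 (SE 0.183) for miR-144-5p and by 2.96 (SE 0.408) for miR-144-3p. These SEs treat the miRNAs as independent, although they come from the same libraries. Fewer red cells with unchanged miR-144 per cell would not give these differences. As miR-144-3p itself rose, miR-144 per cell may have changed, so a loss of red cells cannot be excluded. Depth does not account for the fall of miR-451a. With genotype in the model, miR-451a changed by -0.0705 log2 (SE 0.0858) per doubling of depth, and the libraries span 1.9 doublings. The genotype change of miR-451a with depth in the model was -1.28 (SE 0.119). That of miR-144-3p was 1.66 (SE 0.205), although miR-144-3p itself went down with depth, with a slope of -0.756 (SE 0.148). In 2 pairs of libraries with depths within 1.07 times of each other, wild-type miR-451a was at least 2.17 times the mutant value, but both pairs share Ago2 D598A replicate 3 and so rest on 1 mutant library. A candidate explanation is the loss of AGO2 cutting of the pre-miR-451a hairpin, which was not tested apart from the genotype. miR-451a was lowered 2.42-fold, not lost, and the cells that the remaining miR-451a came from were not determined. A change in red cell maturity, changed ends of the molecules and an unlabelled batch or litter stay open and untested. So do fewer red cells with more miR-144 per cell.

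Of the 196 hairpins, 20.9% had a changed ratio of lesser to major arm. A bound of 5% was set earlier for altered cell composition or transcription, but it was wrong: it took every cell type to have the same arm ratio, which was not measured here. An altered mix of cells therefore cannot be told apart from a change within cells. Of the 41 changed hairpins, 30 had no family member of the same number and arm in the table (of 121 such hairpins). The other 11 had one (of 75). This check goes by name, so it misses near-identical miRNAs with another number or absent from the table. Sharing of reads between near-identical miRNAs cannot be told apart from a real change in either class, because the reads are not at hand. If AGO2 cuts the lesser arm of well-paired duplexes, hairpins with a longer helix may gain it in the mutant, and Spearman's rho between helix length and change of the ratio was 0.185 over 179 hairpins (permutation p = 0.0136, adjusted p = 0.0227 over 5 tests; Pearson's r 0.191, 95% bootstrap range of rho 0.0376 to 0.333). The size of the change showed no such relation over the same hairpins (rho 0.00489, permutation p = 0.947). Hairpins are not independent replicates and the relation is weak, and cutting of the lesser arm leaves unexplained the larger class, the 28 of 41 changed ratios in which the lesser arm was lower. Altered loading between AGO proteins or altered stability of each arm stays open and untested, as do batch and litter.

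miR-2137, miR-6236, miR-6238, miR-6239 and miR-6240, with a median log2 fold change of -1.73, fell together. Their annotated hairpins were poorly paired in part: 3 of 5 (miR-6236, miR-6238 and miR-6240) lay below 61.9% paired bases, the 10th percentile of the 456 folded hairpins, and 2 (miR-2137 and miR-6239) lay above the 25th percentile of 66.1%. Counting of fragments of longer RNAs could therefore not be settled and cannot be told apart from a change in miRNAs without the reads. No single library decided the size of the fall, since the median with 1 library left out ran from -2.14 to -1.19 (SE 0.43), the latter without wild-type replicate 2. The 5 were picked from the largest falls, and the calls of 4 of them ended with some library left out. The log2 fold changes where calls ended were -1.96 and -2.16 for miR-2137, -1.72 and -1.57 for miR-6240, -1.499 to -0.969 for miR-6236, and -0.94 and -1.01 for miR-6238. Carry-over of degraded RNA that differed between the placentas may contribute and was not tested.

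For chance, 3 libraries against 3 allow 10 splits, too few for a share under 0.05. Of these 10 splits, 1 (the real one) gave as many changed miRNAs, 82 against at most 2 in another split. For arm ratios it was also 1 of 10, with 41 against at most 1. For lists it was 1 of 10, with 6 against at most 5, so other splits of the libraries also moved several lists by camera. Each other split mixes the genotypes 2 against 1, which keeps part of a genotype difference and adds spread within groups. Counts from the other splits are therefore no baseline for chance.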
